A study of Arabidopsis thaliana with 16 samples.

How the data were processed

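Roots of dark-grown Arabidopsis seedlings were compared on 16 Affymetrix arrays of 22810 probe sets, in 8 groups of 2 arrays. Per the labels, seedlings grew for 3 days in the dark at 22 °C. In the ethylene experiment, wild-type Col-0 (Col) and the aux1-7 mutant (aux1, which lacks a functional auxin influx carrier) were kept for 4 h in air or in 10 ppm ethylene. In the auxin experiment, Col and the ein2-5 mutant (ein2, which lacks a central component of ethylene signalling) were sprayed with a 0.01% ethanol solution (mock) or with 1 µM indole-3-acetic acid (IAA) and kept for 4 h in the dark. Roots were taken without the hypocotyl, and the series describes the 2 arrays of a group as biological replicates.

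The deposited values were GCRMA expression values per probe set on a log2 scale. The labels name GCRMA, which by default corrects background, normalizes quantiles across arrays and summarises each probe set. Its version, its settings and the set of arrays normalized together were not stated. The log2 scale was read from the values, which ran from 1.24 to 15.40. Array medians lay between 5.874 and 6.004, and the correlation between the 2 arrays of a group lay between 0.993 and 0.998. The values were used as deposited. For arrays there is no count depth, and the number of arrays limits the precision.

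The annotation supplied listed 14016 of the probe sets. It gave 1 gene for 13436 of them, several genes for 503 and a name without a locus code for 77. Another 8730 probe sets were unlisted, and 64 were controls. Controls, probe sets of several genes and the 77 without a locus code were left out. For each of the 144 loci with 2 or more probe sets, the probe set with the highest mean over all arrays was kept. Each unlisted probe set was kept as a feature of its own, a departure from the plan made because many auxin and ethylene genes had no named probe set. Features above 4 on the log2 scale in at least 2 arrays were tested. These were 13836 features, of which 7642 had a locus code and 6194 were unlisted, and they are called genes in all counts. Names of genes were used only where the annotation gave them, so unlisted probe sets were counted but not named.

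limma 3.58.1 in R 4.3.3 fitted a mean per group over all 16 arrays, which left 8 residual degrees of freedom, and eBayes added 3.39 prior degrees of freedom. Each change is a difference of log2 means, given as ± its moderated standard error (SE) with n = 2 arrays in each group. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 13836 genes, two-sided. The 8 comparisons were ethylene against air in Col and in aux1, IAA against mock in Col and in ein2, the difference between the genotypes for each treatment (the interaction), aux1 against Col in air, and ein2 against Col in mock. The 2 experiments shared no array.

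Gene lists were tested with limma's camera at a preset correlation of 0.01, two-sided, with adjustment over the lists of a comparison, and again with an estimated correlation. Before the data were examined, 24 lists with 346 loci were fixed. Of these loci 45 had a named probe set and 30 were tested. Only 3 lists had at least 3 tested members: GH3 genes, other auxin response markers, and expansins with xyloglucan endotransglucosylases/hydrolases (XTH). After the annotation had been seen, 21 gene families were added, and 19 of them had enough tested members. Sets of genes called in 1 experiment were measured in the other, so that the changes used to select and to measure shared no array. The spread per gene behind the calls came from all 16 arrays, so selection was not fully independent of the other experiment. The overlap of calls, which shared this spread, was tested with Fisher's exact test across genes, which are not independent replicates. The share of the Col response kept in a mutant was measured on genes that changed at least 2-fold between 2 arrays of 1 replicate number in Col. Their change was then taken from the Col arrays of the other number and set beside that of the mutant arrays.

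The rule for named genes was fixed at the same time as the lists. For each treatment comparison it took the 8 largest rises and 8 largest falls among called genes with a locus code in which both treated arrays lay on the same side of both control arrays. For interactions and genotype comparisons it took the 5 largest per direction. Where fewer than 5 genes were called it took the 5 smallest p values. It also took members of lists and 11 markers chosen in advance, of which GH3.3 and LBD29 had a tested named probe set. AUX1 and EIN2 had no named probe set, so the mutated genes were not analysed here.

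The other settings fixed in advance were median centring, quantile normalization, no filter, a filter at 6, an intensity trend in eBayes, averaged probe sets, a fit within the arrays of 1 experiment, a size limit of 2-fold, a replicate block, and each array left out in turn. A change of the pseudocount was planned for linear values and was not run, since the values were on a log scale. Chosen after the data were seen were a fit on named loci only, a fit on every probe set, and a replicate block within each experiment. The differences between replicates 1 and 2 correlated by 0.31 to 0.42 over the 6 pairs of groups in the ethylene experiment, by 0.104 to 0.40 over the 6 pairs in the auxin experiment, and by -0.14 to 0.02 across the experiments. Arrays of 1 number thus deviated together within an experiment, although the labels do not say what the number marks. The fit without a block was kept as fixed in advance, and the block is given beside results that it changed. This reading was made after both fits had been seen. The procedure was tested on simulated changes of 1.5-, 2- and 4-fold, split over 200 probe sets per comparison whose means lay clear of the filter. The simulated noise was independent, without the shared deviation of a replicate number, so recovery on the real arrays can differ. Of the probe sets changed 2-fold, 71.6% to 88.1% were recovered in the 6 plain comparisons and 38.8% to 47.8% in the 2 interactions. At 4-fold the shares were 97.0% to 100% and 81.8% to 86.4%. Between 2 and 15 unchanged features were called. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.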

Results

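Expression was measured on 16 arrays, with 2 arrays in each of 8 groups: Col in air, Col in ethylene, aux1 in air, aux1 in ethylene, Col in mock, Col in IAA, ein2 in mock and ein2 in IAA. The number of arrays limits the precision, and array medians spanned 5.874 to 6.004 on the log2 scale. All changes below are log2 differences ± SE with n = 2 arrays per group. The highest lower quartile of an array was 2.55, and group means under it were taken as near background, where the size of a change (and of a difference between changes) is limited by the background. Such means entered changes of XTH26, AT5G04120, CSLC12, AT2G39690, GH3.1, AT5G14650, AT1G22900, AT4G39720, AT4G26790, AT5G37690 and FACT, and of AT5G19890 in ein2. Counts with a replicate block, a separate effect of the replicate number within each experiment, are given where they differed by over 1.5 times.

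The first comparison asked which root genes responded to ethylene in the wild type. The largest rise was that of the class III peroxidase gene AT5G19890, at 6.49 ± 0.55 (89.9-fold, adjusted p = 3.07e-05). Other rises were those of AT5G40590 (4.36 ± 0.43), of the acyltransferase gene AT2G39980 (4.25 ± 0.22), of AT5G62280 (3.74 ± 0.39) and of AT1G76470 (3.70 ± 0.46). XTH26 (AT4G28850), a cell wall enzyme of root hairs, rose by 3.94 ± 0.50, and ARL (AT2G44080), which promotes cell expansion, rose by 3.901 ± 0.35. RTE1 (AT2G26070), a regulator of the ETR1 ethylene receptor, rose by 2.92 ± 0.18, while EIN3 (AT3G20770), a transcription factor of ethylene signalling, stood at -0.06 ± 0.14 (adjusted p = 0.894). Among genes with a locus code, the largest falls were those of the polygalacturonase gene AT2G43890 (-4.66 ± 0.80) and of the wall-loosening protein EXPA8 (AT2G40610, -4.45 ± 0.19), followed by AR781 (AT2G26530, -3.59 ± 0.55), AT5G04120 (-3.52 ± 0.28), AT3G19320 (-3.42 ± 0.17), the aldo/keto reductase gene AT5G62420 (-3.32 ± 0.43) and EXPB1 (AT2G20750, -3.29 ± 0.15). The SD of AR781 between the Col air arrays was 1.59. Over all genes, Col air had the widest differences between its replicates (SD 0.43, against 0.26 to 0.35 in the other groups). RR16 (AT2G40670), a cytokinin response regulator, rose by 1.81 ± 0.28 (adjusted p = 0.00177).

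Among the 10 tested expansins and XTH genes, 1 rose and 4 fell with ethylene in Col, and 2 rose and 4 fell when adjusted over the list alone. With the replicate block EXPA7 (adjusted p = 0.0243) also rose. The falls were those of EXPA8, XTH21 (-1.66 ± 0.23), EXPA4 (-1.63 ± 0.35) and EXPA15 (-1.31 ± 0.21). The list was called lower (median -0.40, adjusted p = 0.0243). It was not called with an estimated correlation (adjusted p = 0.207), after median centring (0.0581), without Col ethylene replicate 2 (0.0857), or without Col air replicate 1 (0.197), where its median was -0.14. EXPA4 was not called without Col air replicate 2 or Col ethylene replicate 2 (0.0772 to 0.086). Of the 4 tested GH3 genes, which encode enzymes that conjugate auxin to amino acids, GH3.17 fell by 1.199 ± 0.13, and 2 members fell when adjusted over the list alone. GH3.3 stood at -1.74 ± 0.75 (adjusted p = 0.216), with an SD of 2.40 between the Col air arrays. The GH3 list was called lower (median -1.23, adjusted p = 0.0243), not with an estimated correlation (adjusted p = 0.0957), after median centring (0.0505) or without Col air replicate 1 (0.197), where its median was -0.25. Of the 3 other auxin response markers only LBD29 (AT3G58190), a regulator of lateral root formation, was called, at -1.02 ± 0.29 (adjusted p = 0.0478), and the list was not (adjusted p = 0.589).

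In all, 1219 of 13836 genes were called for ethylene in Col, 561 higher and 658 lower. The count was 720 without Col ethylene replicate 1 and 675 in a fit on the arrays of the ethylene experiment alone. With a size limit of 2-fold it was 511, and among named loci only it was 611. Of the named genes, the peroxidase gene AT3G49960 (3.81 ± 0.80, adjusted p = 0.0109) was not called without Col air replicate 2 (2.42, adjusted p = 0.067) or without Col ethylene replicate 1 (0.0832). The peroxidase gene AT1G14550 (-3.16 ± 0.89, adjusted p = 0.0499) lost its call with any of 13 arrays left out (adjusted p from 0.0659 to 0.279), all except Col air replicate 2 and both aux1 ethylene arrays. It was not called with no filter (0.122), in the ethylene experiment alone (0.188), with averaged probe sets (0.0504), among named loci only (0.0511) or with every probe set (0.0506) either, and LBD29 was not called in the first 2 of these settings (0.106 and 0.135) or after quantile normalization (0.0519). The call of AT3G49960 (0.0668) and that of EXPA4 (0.0755) also ended in the ethylene experiment alone. The change of AT1G14550 was -1.52 without Col air replicate 1 and -4.80 without Col air replicate 2. LBD29 lost its call with any of 11 arrays left out (adjusted p from 0.0524 to 0.331), all except the aux1 arrays and Col ethylene replicate 2.

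**Figure D1:**
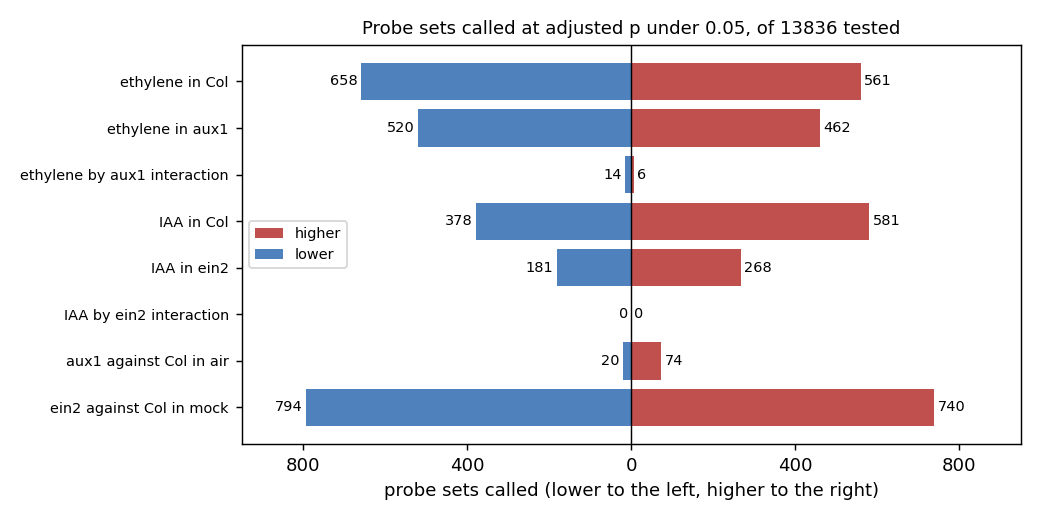
Bars give the number of genes called higher (right) and lower (left) at an adjusted p under 0.05 in each of the 8 comparisons, of 13836 tested. Ethylene called 1219 genes in Col and 982 in aux1, IAA called 959 in Col and 449 in ein2, and the interactions called 20 and 0.

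The response to ethylene was then measured in aux1, to ask which part of it took place without the auxin carrier. AT5G19890 rose by 5.30 ± 0.55, AT2G39980 by 4.37 ± 0.22, AT1G76470 by 4.18 ± 0.46, AT5G40590 by 4.07 ± 0.43, and ARL by 3.34 ± 0.35. AT4G38410 (3.68 ± 0.38), AT5G24570 (3.595 ± 0.49) and the 2-oxoglutarate oxygenase gene AT5G59540 (3.47 ± 0.28) also rose, and RTE1 rose by 2.74 ± 0.18. Among genes with a locus code, the largest falls were those of AT1G03820 (-3.40 ± 0.29), AT5G62420 (-3.10 ± 0.43), AT5G62330 (-2.83 ± 0.21), AT5G04120 (-2.78 ± 0.28), AT5G01740 (-2.71 ± 0.52), the dirigent gene AT4G11210 (-2.58 ± 0.18), EXPB1 (-2.36 ± 0.15) and EXPB3 (AT4G28250, -2.36 ± 0.55). Among the 10 expansins and XTH genes none rose and 4 fell, both over all genes and adjusted over the list alone, among them EXPA4 (-2.07 ± 0.35), EXPA15 (-1.85 ± 0.21) and XTH21 (-0.89 ± 0.23, adjusted p = 0.0387). With the replicate block XTH18 rose (adjusted p = 0.0173) and LBD29 fell (0.00245). The list of expansins and XTH genes was not called (adjusted p = 0.159), and neither were the GH3 genes (adjusted p = 0.23), of which GH3.17 fell by 1.14 ± 0.13, or the other auxin response markers (adjusted p = 0.985).

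For ethylene in aux1, 982 genes were called, 462 higher and 520 lower. The count was 513 without aux1 air replicate 2, 598 without aux1 ethylene replicate 2, 497 in a fit on the ethylene experiment alone, 407 with a size limit of 2-fold, 491 among named loci only, and 1483 with the replicate block. AT5G01740 was not called without aux1 air replicate 1 or aux1 ethylene replicate 1 (adjusted p of 0.0527 to 0.065). EXPB3 was not called without either aux1 air array or without aux1 ethylene replicate 2 (0.0761 to 0.108), where its change was -1.22. It was not called with no filter (0.0711) or in the ethylene experiment alone (0.129) either. XTH21 lost its call with any of 7 arrays left out (0.0564 to 0.239), with a change of -0.58 without aux1 ethylene replicate 1. It was also not called after median centring (0.0567) or quantile normalization (0.0505), with no filter (0.0846), or in the ethylene experiment alone (0.143). Of the genes called in Col, 330 of 561 higher genes and 318 of 658 lower genes were called the same way in aux1. A further 1 gene in each direction was called the opposite way.

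A direct test of the difference between the genotypes called 20 genes, 6 with a higher and 14 with a lower ethylene effect in aux1 than in Col. CSLC12 (AT4G07960), a synthase of the xyloglucan backbone, had an effect of 3.295 in Col and 0.23 in aux1, a difference of -3.06 ± 0.33 (adjusted p = 0.00316). The neighbouring DUF241 genes AT4G35200 (-2.97 ± 0.35) and AT4G35210 (-2.51 ± 0.24) rose by 2.78 and 2.49 in Col and stood at -0.19 and -0.02 in aux1. AT2G39690 (-2.33 ± 0.22) and AT5G60630 (-1.56 ± 0.22) rose by 2.42 and 1.64 in Col and stood at 0.09 and 0.08 in aux1. EXPA8 fell by 4.45 in Col and by 1.78 in aux1, a difference of 2.67 ± 0.26 (adjusted p = 0.00153). AT3G19320 also fell less in aux1, by 1.33 against 3.42 in Col, a difference of 2.09 ± 0.24. AT5G28630 (1.27 ± 0.18) was called lower in Col (-0.96, adjusted p = 0.00062) and was not called in aux1 (0.31, 0.203). A difference of the same sign came about otherwise for the GASA family gene AT2G18420 (1.01 ± 0.13). It rose in both, by 0.47 in Col and by 1.48 in aux1. None of the 3 lists was called for the difference (adjusted p of 0.371 to 0.418), and RR16 stood at -1.46 ± 0.40 (adjusted p = 0.391).

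The count of 20 was 34 without Col air replicate 1, 87 without Col air replicate 2, 6 with a filter at 6, and 11 among named loci only. In a fit on the ethylene experiment alone it was 3, and AT4G35210 was then the only named gene still called (adjusted p of 0.0878 for EXPA8 to 0.263 for AT2G18420 among the others). With an intensity trend in eBayes, AT2G18420 (0.237) and AT5G60630 (0.0766) were not called. AT5G28630 and AT5G60630 were each not called with any of 4 arrays left out (adjusted p of 0.0548 to 0.0838 and 0.0548 to 0.09). These were Col ethylene replicate 1, aux1 air replicate 1 and aux1 ethylene replicate 2 for both, Col ethylene replicate 2 for AT5G28630, and aux1 air replicate 2 for AT5G60630.

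**Figure D2:**
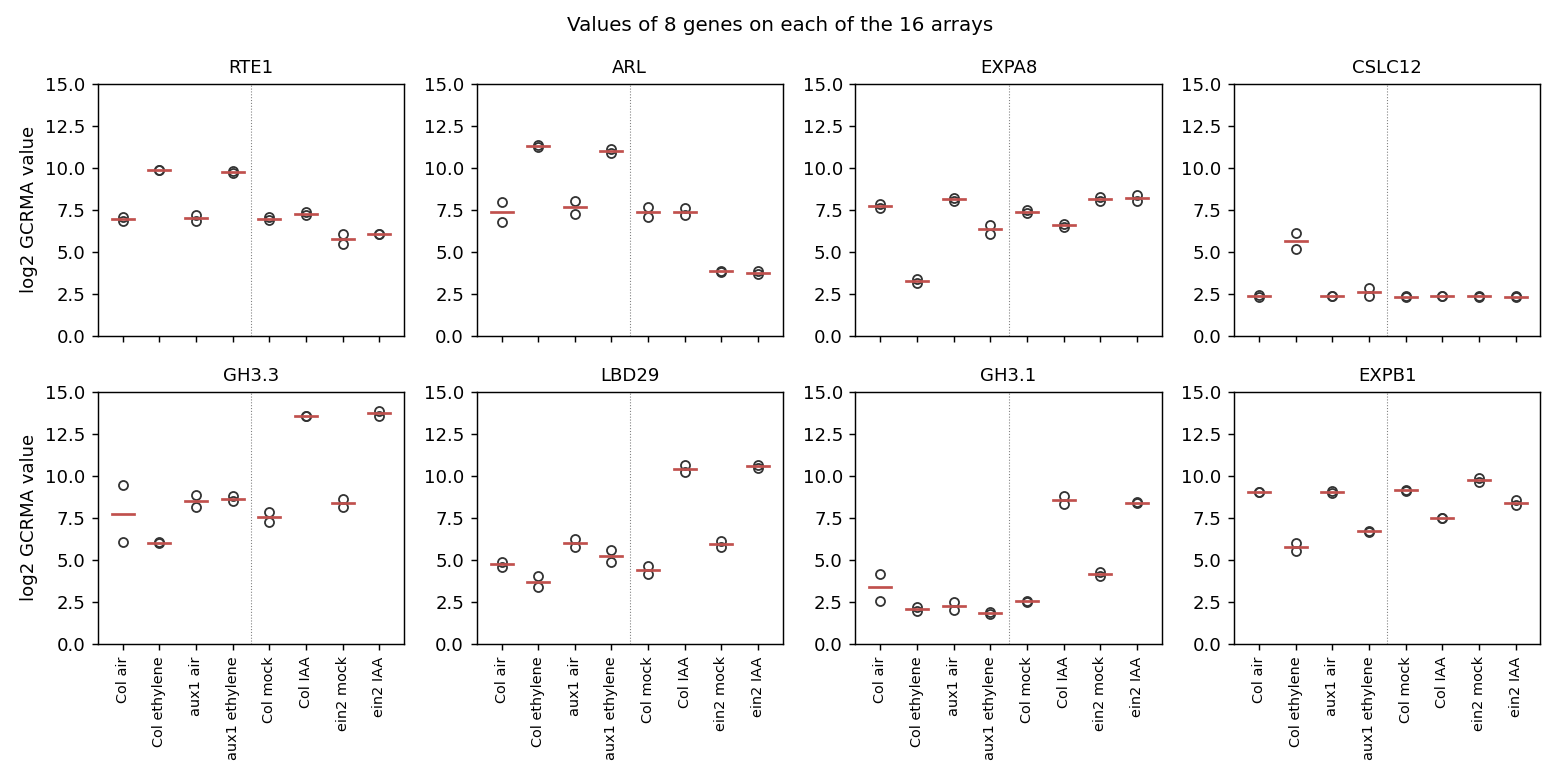
Each circle is the log2 GCRMA value of 1 array and each bar the mean of the 2 arrays of a group, for 8 genes in the 8 groups, with the ethylene experiment left of the dotted line. RTE1 and ARL were higher in ethylene in both genotypes, CSLC12 was raised in Col in ethylene (a change of 3.295, against 0.23 in aux1), and GH3.3, LBD29 and GH3.1 were higher with IAA in both genotypes.

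In the auxin experiment the question was which root genes responded to IAA in the wild type. The GH3 genes GH3.1 (AT2G14960, 6.05 ± 0.39, from a Col mock mean of 2.51) and GH3.3 (AT2G23170, 6.02 ± 0.75, 64.9-fold) rose, and WES1 (AT4G27260), also known as GH3.5, rose by 3.71 ± 0.17. LBD29 rose by 6.02 ± 0.29, as did AT1G64405 (5.71 ± 0.16), the polygalacturonase gene AT5G14650 (4.87 ± 0.30), AT4G37295 (4.87 ± 0.36) and the dirigent gene AT1G22900 (4.73 ± 0.18). The falls were smaller: AT4G01140 (-1.92 ± 0.13), AT3G18450 (-1.87 ± 0.25), AT5G38820 (-1.81 ± 0.34), the pectin methylesterase inhibitor gene AT4G25250 (-1.80 ± 0.21), AT3G21340 (-1.75 ± 0.23), AT5G62420 (-1.72 ± 0.43), EXPB1 (-1.64 ± 0.15) and AT3G19320 (-1.62 ± 0.17). The GH3 list was called higher (adjusted p = 2.13e-08, and 0.00111 with an estimated correlation), with 3 of 4 members called and 4 when adjusted over the list alone. Of the 3 other auxin response markers, LBD29 and LBD16 (1.18 ± 0.20) rose, 2 also when adjusted over the list alone, and HAT2 did not pass (0.19 ± 0.16). That list was called (adjusted p = 7.06e-05, and 0.00508 with an estimated correlation). Of the 10 expansins and XTH genes, EXPA4 (1.41 ± 0.35) and XTH20 (0.91 ± 0.24) rose while XTH21 (-1.08 ± 0.23) and EXPA8 (-0.80 ± 0.19) fell, the same 2 and 2 counts when adjusted over the list alone, and the list was not called (adjusted p = 0.779).

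For IAA in Col, 959 genes were called, 581 higher and 378 lower. The count was 405 and 487 without Col mock replicate 1 and 2, 410 and 510 without Col IAA replicate 1 and 2, 312 with a size limit of 2-fold, 518 among named loci only, and 1566 with the replicate block. AT5G38820 was not called without Col mock replicate 2 or Col IAA replicate 1 (adjusted p of 0.0764 to 0.0864), and AT5G62420 was not called with any of the 4 Col mock and IAA arrays left out (0.101 to 0.193). Without 1 of those 4 arrays, EXPA8 (0.0693 to 0.174), XTH21 (0.0506 to 0.117) and EXPA4 (0.0698 to 0.23) were not called either. LBD16 was not called without Col mock replicate 1 or Col IAA replicate 1 (0.0541 to 0.0582). XTH20 lost its call with any of 10 arrays left out (0.0569 to 0.246), all except the air arrays and the ein2 IAA arrays, and with a replicate block over both experiments (0.0532). With no filter, AT5G62420 (0.086), XTH20 (0.0918) and EXPA4 (0.0804) were not called, and AT5G62420 was not called in the auxin experiment alone (0.0724).

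The same treatment was measured in ein2, to ask which part of the IAA response took place without EIN2. GH3.3 rose by 5.31 ± 0.75, AT5G14650 by 4.72 ± 0.30, LBD29 by 4.58 ± 0.29, GH3.1 by 4.23 ± 0.39, AT4G37295 by 4.097 ± 0.36, AT1G64405 by 3.99 ± 0.16, AT1G22900 by 3.86 ± 0.18 and WES1 by 3.69 ± 0.17. The falls were those of AT5G02000 (-1.62 ± 0.21), the oxidase gene AT1G19900 (-1.59 ± 0.19), AT4G01140 (-1.58 ± 0.13), the peroxidase gene AT2G39040 (-1.55 ± 0.17), AT3G21340 (-1.44 ± 0.23), AT1G49030 (-1.37 ± 0.22), AT3G49190 (-1.36 ± 0.30) and EXPB1 (-1.32 ± 0.15). The GH3 list (adjusted p = 7.06e-09, and 0.000903 with an estimated correlation) had 3 members called higher, and 3 when adjusted over the list alone. The other auxin response markers (adjusted p = 4.67e-06, and 0.00228 with an estimated correlation) had 2 called higher by both adjustments, LBD29 and LBD16 (1.57 ± 0.20). The expansins and XTH genes were not called (adjusted p = 0.289), with 0 members called over all genes, 1 lower over the list alone, and XTH21 lower with the replicate block (adjusted p = 0.00649).

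For IAA in ein2, 449 genes were called, 268 higher and 181 lower. The count was 231 and 208 without ein2 mock replicate 1 and 2, 206 and 231 without ein2 IAA replicate 1 and 2, 209 with a size limit of 2-fold, 219 among named loci only, and 733 with the replicate block. AT3G21340 (adjusted p = 0.0654) and AT1G49030 (0.0569) were not called without ein2 mock replicate 2, and AT3G49190 was not called with any of the 4 ein2 arrays left out (0.103 to 0.213) or with no filter (0.0758). Of the genes called in Col, 204 of 581 higher and 125 of 378 lower genes were called the same way in ein2, and 0 the opposite way.

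The difference in IAA response between ein2 and Col called 0 genes with limma, and 622 had an unadjusted p under 0.05, where 691.8 were expected by chance. The 5 genes with the smallest p among those with a locus code were not called. They were AT3G47480, an EF-hand protein gene (-2.29 ± 0.29, adjusted p = 0.0625), AT1G64405 (-1.72 ± 0.23, 0.0625), AGO7 (AT1G69440), an argonaute protein (1.26 ± 0.19, 0.135), AT4G39720 (0.96 ± 0.16, 0.175) and the GDSL lipase gene AT4G26790 (1.17 ± 0.20, 0.183). GH3.1 (-1.82 ± 0.55, adjusted p = 0.955) and LBD29 (-1.43 ± 0.40, 0.875) were not called. Means with IAA were close in Col and ein2 for AT1G64405 (9.565 and 9.552), LBD29 (10.412 and 10.541) and GH3.1 (8.557 and 8.389). Their mock means were higher in ein2 (5.563, 5.956 and 4.16) than in Col (3.853, 4.396 and 2.51). AT3G47480 differed otherwise, with an IAA effect of 2.69 in Col and 0.40 in ein2 and a mock difference of 0.02. With the replicate block 5 genes were called, among them AT3G47480, AT1G64405 and LBD29 (adjusted p = 0.0442 each). The count was 6 without Col mock replicate 2, 3 without ein2 mock replicate 1, 3 with no filter, and 2 among named loci only. It was 2 each without Col IAA replicate 1 or 2 and without aux1 air replicate 1 or 2.

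Genes called in 1 experiment were then measured in the other, to ask how far the hormone responses were shared and whether the sharing required AUX1 or EIN2. The 378 genes lowered by IAA had a median of -0.40 with ethylene in Col, where 146 of them fell and 14 rose (camera adjusted p over the 12 tests = 2.86e-32, and 0.000129 with an estimated correlation). In aux1 their median was -0.15, with 69 called lower and 17 higher (adjusted p = 9.68e-06, and 0.0163 with an estimated correlation). Their ethylene effect differed between the genotypes by a median of 0.23 (adjusted p = 6.06e-28, and 0.000129 with an estimated correlation). EXPA8, EXPB1, AT3G19320 and AT5G62420 were among the genes that fell with both hormones in Col. The 581 genes raised by IAA had a median of 0.11 with ethylene in Col (adjusted p = 0.00576, and 0.238 with an estimated correlation), with 69 called higher and 36 lower, and -0.06 in aux1 (adjusted p = 0.0878), with 32 called higher and 35 lower. AT4G35200 and AT4G35210 belonged to these, with rises of 2.38 and 2.16 with IAA in Col. CSLC12, AT2G39690 and AT5G60630, whose ethylene effect was also lower in aux1, did not. They stood at 0.04, 0.01 and 0.01 with IAA in Col (adjusted p of 0.963 to 0.985). For the 581 genes the difference between the genotypes was -0.15 (adjusted p = 3.22e-08, and 0.0316 with an estimated correlation). In the alternative settings, here and in the reverse direction, sets were judged on a camera p not adjusted over the 12 tests. The call of the median of 0.11 was lost without Col ethylene replicate 1 (0.02), Col air replicate 2, Col mock replicate 1 or Col IAA replicate 2 (0.07 each), and with a size limit of 2-fold, where the median was -0.02. That median was 0.18 without Col ethylene replicate 2 and 0.07 without Col IAA replicate 1. The set raised by IAA was called lower in aux1 without aux1 air replicate 2 (-0.07), aux1 ethylene replicate 1 (-0.10), Col mock replicate 1 (-0.11) or either Col ethylene array (-0.06), and its difference of -0.15 was -0.10 and -0.23 without Col ethylene replicate 1 and 2. For the set lowered by IAA, the medians in Col and aux1 were -0.61 and -0.26 without Col mock replicate 2 and -0.63 and -0.26 without Col IAA replicate 1, where the difference was 0.38.

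In the reverse direction, the 658 genes lowered by ethylene had a median of -0.25 with IAA in Col (adjusted p = 1.5e-14, and 0.00277 with an estimated correlation) and -0.16 in ein2 (1.02e-08, and 0.0116). The difference between ein2 and Col was 0.08 (adjusted p = 0.000202, and 0.053 with an estimated correlation). The 561 genes raised by ethylene had a median of 0.03 with IAA in Col (adjusted p = 0.0243, and 0.45 with an estimated correlation), 0.0044 in ein2 (0.0878), and a difference of -0.05 (0.113), which had an unadjusted camera p of 0.0243 with the replicate block (median -0.07). Their median in Col was not called without Col mock replicate 1 (0.0036) or Col IAA replicate 2 (0.0089), and was 0.10 without Col mock replicate 2. In ein2 it passed without either Col mock array (0.0099), ein2 mock replicate 1 (-0.0083) or ein2 IAA replicate 2 (0.03), and the difference passed without Col air replicate 1 (-0.07), Col mock replicate 2 (-0.11) or Col IAA replicate 1 (-0.09). The difference of 0.08 in the lowered genes was 0.12 without Col mock replicate 2. Among all 13836 genes, 69 were called higher for both hormones in Col against 23.6 expected (Fisher's exact p = 4.89e-16), and 146 lower for both against 18.0 expected (8.34e-97). Opposite calls numbered 14 against 15.3 expected (0.894) and 36 against 27.6 expected (0.11). The 215 genes called the same way and the 50 called in opposite ways became 105 and 32 without Col mock replicate 1, and 138 and 25 without Col mock replicate 2. They became 125 and 26 without Col IAA replicate 1, 124 and 31 without Col IAA replicate 2, 69 and 16 with a size limit of 2-fold, and 385 and 93 with the replicate block.

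**Figure D3:**
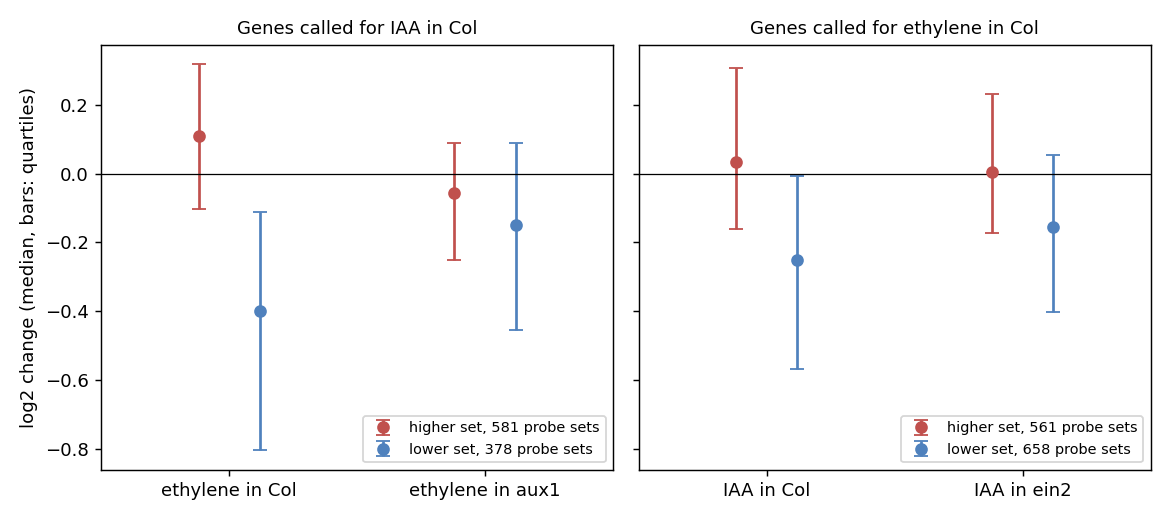
Points are medians and bars the quartiles of log2 changes, of genes called for IAA in Col measured with ethylene (left) and of genes called for ethylene in Col measured with IAA (right). The genes lowered by IAA had a median of -0.40 with ethylene in Col and -0.15 in aux1.

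Calls alone cannot give the share of a response that a mutant kept, since picking genes on Col arrays inflates the Col change. Among genes picked in 1 replicate number and measured in the other, aux1 kept 77.3% and 96.7% of the median rise with ethylene in the 2 picks (325 and 425 genes), and 75.5% of the median fall in both (391 and 291 genes). For IAA, ein2 kept 72.9% and 86.7% of the median rise (320 and 256 genes), and 65.2% and 69.9% of the median fall (230 and 153 genes). These are values without a test. With the control array of the other number, the mean share of the IAA fall was 93.4% in place of 67.5%.

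Against Col in air, aux1 had higher values of 2 lipid transfer protein genes, AT2G18370 (5.76 ± 0.49, 54.3-fold, adjusted p = 0.000168) and AT3G58550 (5.28 ± 0.72), of the GDSL lipase gene AT5G37690 (4.63 ± 0.54), of the peroxidase gene AT2G35380 (4.36 ± 0.39) and of AT2G22510 (4.24 ± 0.39). Lower were the GDSL lipase gene AT2G03980 (-2.59 ± 0.40), BGLU24 (AT5G28510), a beta-glucosidase (-1.83 ± 0.29), the DUF241 gene AT2G17070 (-1.45 ± 0.23), AT4G37220 (-1.41 ± 0.24) and WAG2 (AT3G14370), a kinase that phosphorylates auxin efflux carriers (-1.23 ± 0.18). LBD29 stood at 1.26 ± 0.29 (adjusted p = 0.0923, and 0.000661 with the replicate block). No list was called (adjusted p of 0.364 for the other auxin response markers, 0.432 for the expansins and XTH genes and 0.496 for the GH3 genes), and XTH18 (0.0376) and XTH19 (0.0245) were lower only with the replicate block. The photosystem and light-harvesting family, a marker of shoot tissue, had a median of 0.26 over 16 members (adjusted p = 0.282). In all 94 genes were called, 74 higher and 20 lower. The count was 192 without Col air replicate 2, 145 without aux1 air replicate 1, 51 in a fit on the ethylene experiment alone, 44 among named loci only, and 171 with the replicate block. Without aux1 air replicate 2, AT3G58550 (adjusted p = 0.053), AT2G03980 (0.1), BGLU24 (0.116), AT2G17070 (0.127) and AT4G37220 (0.158) were not called, and AT2G17070 was not called without Col air replicate 1 either (0.0816), nor AT4G37220 with no filter (0.0595). In the ethylene experiment alone none of the 5 lower genes named was called (adjusted p from 0.102 for WAG2 to 0.214 for AT4G37220).

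Against Col in mock, ein2 had higher values of AT5G37690 (6.55 ± 0.54, adjusted p = 1.52e-05, from a Col mock mean of 2.096), AT4G28940 (4.60 ± 0.17), AT2G35380 (4.59 ± 0.39), the GDSL lipase gene AT2G23540 (4.56 ± 0.46) and the nucleobase transporter gene AT1G49960 (4.47 ± 0.38). Lower were the peroxidase gene AT1G49570 (-5.91 ± 0.51), the wound-responsive family gene AT4G10270 (-4.66 ± 0.48), AT1G19530 (-3.71 ± 0.19), AT5G59540 (-3.61 ± 0.28), ARL (-3.55 ± 0.35) and RTE1 (-1.19 ± 0.18). Of the genes with the largest rises with IAA in Col, GH3.1 (1.65 ± 0.39, adjusted p = 0.0182), LBD29 (1.56 ± 0.29, 0.00452) and AT1G64405 (1.71 ± 0.16, 3.88e-05) were higher in mock-treated ein2. GH3.3 (0.84, 0.541), AT4G37295 (0.84, 0.169), AT5G14650 (0.12, 0.854), AT1G22900 (0.06, 0.891) and WES1 (0.02, 0.963) were not called, and the IAA-raised set was not tested in this comparison. GH3.17 was also higher (0.50 ± 0.13, 0.028), and was not called for IAA in either genotype (0.242 in Col). The GH3 list had 2 members called higher by both adjustments and was not called (adjusted p = 0.0736), nor were the other auxin response markers (0.365). The expansins and XTH genes were called higher (adjusted p = 0.00297, and 0.121 with an estimated correlation), with XTH20 (2.43 ± 0.24), EXPA4 (2.19 ± 0.35) and EXPA8 (0.77 ± 0.19) called, 3 of 10 also when adjusted over the list alone, and XTH19 was also higher with the replicate block (adjusted p = 0.0447). The photosystem and light-harvesting family had a median of -0.27 with 3 of 16 members called lower (adjusted p = 0.0827), and its member LHCB4.1 stood at -2.24 ± 0.53 (0.0195). LHCB4.1 was not called without Col mock replicate 1 (-1.09) or either ein2 mock array (0.0586 to 0.0965), with no filter (0.0534) or in the auxin experiment alone (0.0559), and its change was -3.38 without Col mock replicate 2. GH3.1 (0.0636 to 0.113) and EXPA8 (0.0528 to 0.136) were not called with any of the 4 Col and ein2 mock arrays left out. GH3.17 was not called without either Col mock array or ein2 mock replicate 2 (0.101 to 0.189), or after median centring (0.055).

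In all 1534 genes were called between ein2 and Col in mock, 740 higher and 794 lower. The count was 834 and 779 without Col mock replicate 1 and 2, 853 and 857 without ein2 mock replicate 1 and 2, 553 with a size limit of 2-fold, 746 among named loci only, and 2350 with the replicate block. Of the genes raised by ethylene in Col, such as ARL, RTE1 and AT5G19890 (-2.80 ± 0.55 in ein2), 153 were lower in ein2 against 32.2 expected (Fisher's exact p = 2.63e-64). Of the genes lowered by ethylene, such as EXPA4 and EXPA8, 133 were higher in ein2 against 35.2 expected (4.14e-43).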

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

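The tests of array scaling and of a difference between the air arrays were chosen only after the result was seen.

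A test of the difference between the genotypes called 20 genes whose ethylene effect differed between aux1 and Col. The differences (aux1 minus Col, log2) were 2.67 for EXPA8, 2.09 for AT3G19320, 1.27 for AT5G28630 and 1.01 for AT2G18420. They were -3.06 for CSLC12, -2.97 for AT4G35200, -2.51 for AT4G35210, -2.33 for AT2G39690 and -1.56 for AT5G60630. The count was 34 without Col air replicate 1 and 87 without Col air replicate 2, and AT5G28630 and AT5G60630 each lost their call with any of 4 arrays left out. The 581 genes raised by IAA also differed, with a median of -0.15 (-0.10 and -0.23 without Col ethylene replicate 1 and 2). In air these genes were higher in aux1 than in Col by a median of 0.10 (camera adjusted p = 8.69e-06, and 0.0539 with an estimated correlation). This leaves the air arrays open as part of the difference. The 658 genes lowered by ethylene differed in their IAA effect between ein2 and Col by a median of 0.077, or 0.12 without Col mock replicate 2 (adjusted p = 0.000202, and 0.053 with an estimated correlation). Genes picked as lowered by IAA in 1 replicate number were measured in the other. Of their fall, ein2 kept 80.4% and 73.2% for those that ethylene also lowered, against 59.7% and 66.2% for those without an ethylene call. The latter minus the former was -20.7 and -7.1 points (bootstrap bounds over genes -49.5 to 3.6 and -32.4 to 8.4). Among raised genes it was 2.6 and 36.7 points (-20.6 to 21.3 and 13.0 to 50.0). A loss specific to ethylene-lowered genes was thus not shown.

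The pattern weighed here is the smaller ethylene effect in aux1 on the 378 genes lowered by IAA, a median difference of 0.23 (0.38 without Col IAA replicate 1). The median stayed at 0.23 after quantile normalization and was 0.29 after median centring. The deposited arrays were already close in scale, and rescaling moved the median difference of all genes only from -0.02 to -0.003 and 0.04. This test could thus hardly have ended the pattern, and argues only against a scale difference left in the deposited values. A difference between the air arrays alone is argued against, since in ethylene these genes were higher in aux1 than in Col by a median of 0.14 (camera p = 4.27e-14, and 0.000329 with an estimated correlation). In air they were lower by a median of -0.10 (adjusted p = 1.56e-06, and 0.0148), which leaves the air arrays open as part of it. A weaker response of all genes is argued against by genes picked as lowered in 1 replicate number and measured in the other: aux1 kept 52.0% and 44.3% of the fall of those that IAA also lowered (58 and 69 genes), against 90.8% and 81.3% for those without an IAA call. The differences were 38.8 and 37.0 percentage points (bootstrap 95% bounds over genes 20.8 to 60.9 and 24.0 to 50.2). Among genes picked as raised by ethylene they were 24.3 and 21.2 points (1.1 to 57.2 and -6.1 to 47.4). Each pick was measured on 1 pair of arrays per genotype, and the bounds hold these arrays fixed, so they do not measure the spread between arrays. For the lowered genes, the Col falls of the groups also differed in size (-1.66 against -0.75 in the first pick). These values are consistent with the hypothesis that auxin transport by AUX1 is needed for part of the ethylene effect on genes that auxin lowers, which was found and tested on the same arrays, and a difference between the seed stocks stays open and untested.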

How the results depend on the processing

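The fits on named loci only and on every probe set, and the replicate block within each experiment, were chosen only after the data were seen. Median centring, quantile normalization, an intensity trend, averaged probe sets and the fit on every probe set left the counts of called genes within 1.5 times, and the set medians kept their direction and side of the threshold under them. For named genes and lists, 342 results had 9189 alternative values, of which 8961 kept direction and side, 169 lost a call, 59 gained one and 0 reversed. Of the lost calls, 119 were with 1 array left out, 21 in the fit on 1 experiment alone and 14 with no filter. Unless stated, the cause of a change was not tested. Weak signals near the background of about 2 on the log2 scale limit the changes of the genes listed in the report, and a lone array of a group was assumed to vary like the others.

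In a fit on 1 experiment alone, which has fewer residual degrees of freedom, the counts were 675 (ethylene in Col), 497 (ethylene in aux1), 3 (ethylene by aux1) and 51 (aux1 against Col), opposite calls 33, and the median of ethylene-raised genes with IAA in Col 0.0219. A size limit of 2-fold, which passes fewer genes by construction, gave 511 (ethylene in Col), 407 (ethylene in aux1), 312 (IAA in Col), 209 (IAA in ein2) and 553 (ein2 against Col), shared calls 69 and opposite calls 16. It turned the median of IAA-raised genes with ethylene in Col to -0.0176 and left that of ethylene-raised genes with IAA in Col at 0.0159, neither past the threshold. Named loci only, which tests fewer genes, gave 611, 491 and 11 (ethylene in Col, in aux1, interaction), 518, 219 and 2 (IAA in Col, in ein2, interaction), 44 (aux1 against Col) and 746 (ein2 against Col), shared calls 115, opposite calls 25, and 0.0133 for ethylene-raised genes with IAA in ein2.

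A replicate block over both experiments gave 1335 for ethylene in Col, 20 for ethylene by aux1 and 1084 for IAA in Col. A replicate block within each experiment gave 1483 (ethylene in aux1), 1566 (IAA in Col), 733 (IAA in ein2), 5 (IAA by ein2), 171 (aux1 against Col) and 2350 (ein2 against Col), shared calls 385, opposite calls 93, and -0.0722 for the IAA difference of ethylene-raised genes. The first block ended the calls of XTH20 and the GH9 cellulases given with those results, the second that of the GH9 cellulases, and neither any other call of a named gene, list or family. The blocks added the calls given there and those of AT4G17260 (ethylene in Col) and AT1G12010 (ein2 against Col). A filter at 6 gave 6 for ethylene by aux1 and 0.0208 for ethylene-raised genes with IAA in ein2, and no filter gave 3 for IAA by ein2 and 0.0015 for that set.

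The share of the ethylene fall kept in aux1 (75.5%) was 70.6% after median centring, 71.5% after quantile normalization, 76.6% with no filter, 79.1% with a filter at 6, 79.7% for genes of at least 1.5-fold, 79.2% of at least 3-fold, 75.1% with averaged probe sets and 76.1% with the crossed control array. The share of the IAA rise kept in ein2 (79.8%) was 66.2% for genes of at least 1.5-fold. The share of the IAA fall (67.5%) was 62.3% with no filter, 60.3% at 1.5-fold, 76.8% at 3-fold and 93.4% with the crossed control array.

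With each array left out in turn, counts ranged from 720 to 1266 (ethylene in Col), 513 to 1043 (ethylene in aux1), 15 to 87 (ethylene by aux1), 405 to 1016 (IAA in Col), 206 to 477 (IAA in ein2), 0 to 6 (IAA by ein2), 64 to 192 (aux1 against Col) and 779 to 1637 (ein2 against Col). Shared calls ranged from 105 to 239, opposite calls from 25 to 63 and called lists from 6 to 10. For genes raised by IAA, medians ranged from 0.0222 to 0.183 (ethylene in Col), -0.109 to -0.0365 (aux1) and -0.23 to -0.10 (difference). For genes lowered by IAA they ranged from -0.63 to -0.39, -0.26 to -0.11 and 0.20 to 0.38. For genes raised by ethylene they ranged from 0.0036 to 0.10 (IAA in Col), -0.0087 to 0.0311 (ein2) and -0.112 to 0.0100 (difference). For genes lowered by ethylene they ranged from -0.31 to -0.22, -0.22 to -0.12 and 0.05 to 0.12.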

Other observations

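The tests of shoot tissue in either mutant, the test of sprayed plates as the whole cause, the lists of low-oxygen and suberin genes and the 10 added gene set tests were chosen only after results were seen, and the families after the annotation had been seen. For shoot tissue a spread over arrays replaced a bootstrap over genes once its result was seen, because the members varied together (estimated correlation 0.579). For sprayed plates as the whole cause it replaced a camera test, also after both results were seen.

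Different gene families of the cell wall were called with ethylene and with IAA at the preset correlation, and none of the family calls held with an estimated correlation. Of 11 tested expansins, 4 fell with ethylene in Col (median -0.43, adjusted p = 0.00699, and 0.277 with an estimated correlation) and 5 in aux1 (-0.33, 0.0023, and 0.414), while 4 were higher and 1 lower in ein2 than in Col in mock (0.60, 0.0169, and 0.287). GH9 cellulases were called lower with ethylene in aux1 (0.0336, and 0.414 with an estimated correlation) and higher in ein2 (0.0169, and 0.287), and SWEET sugar transporters were called lower with ethylene in Col (0.0173, and 0.312) and aux1 (0.0172, and 0.414). With IAA, trichome birefringence-like genes, which acetylate wall polymers, were called lower as a set in Col (-0.25, 0.0113, and 0.161 with an estimated correlation) and in ein2 (-0.25, 0.00977, and 0.118), with 2 and 0 of 16 members called. For IAA in ein2 the XTH family (0.00977, and 0.118 with an estimated correlation) and the tubulins (0.000876, and 0.233) were also called lower as sets, with 2 of 7 and 1 of 7 members called. Neither set was called for IAA in Col (adjusted p = 0.332 and 0.0543) or for the difference between ein2 and Col (0.555 each). Several of these calls ended when 1 array was left out. With no filter, the SWEET calls (0.0745 in Col, 0.0798 in aux1) and the GH9 calls (0.0798 in aux1, 0.0783 in ein2) ended, and the GH9 call in ein2 also with a filter at 6 (0.0539). In Col, the expansin (adjusted p = 0.068) and SWEET (0.068) calls ended without Col air replicate 1, and the SWEET call also without Col ethylene replicate 1 (0.0678). In aux1, the expansin call ended without aux1 air replicate 1 (0.0624), the SWEET call without aux1 air replicate 1 or aux1 ethylene replicate 1 (0.0842 to 0.0964), and the GH9 call without either of these or either Col air array (0.07 to 0.0858, median -0.13 without aux1 ethylene replicate 1) or with a replicate block (0.0514, and 0.141 within each experiment). With IAA in ein2, the birefringence-like call ended without ein2 mock replicate 2 (0.0578) and the XTH call without ein2 IAA replicate 1 (0.155, median -0.00089).

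The mutants in air or mock differed from Col at genes that the hormones changed. The 561 genes raised by ethylene had a median of -0.21 in ein2 against Col in mock (adjusted p over 10 added tests = 1.19e-11, and 0.0286 with an estimated correlation), and the 658 lowered genes had a median of 0.19 (4.33e-07, and 0.0162). The genes raised by IAA had a median of 0.10 in aux1 against Col in air (8.69e-06, and 0.0539 with an estimated correlation), and those lowered by IAA a median of -0.10 (1.56e-06, and 0.0148). AT1G64405, raised by IAA in both genotypes and singled out here after its values were seen, was higher in aux1 in air (2.11 ± 0.16) and in ein2 in mock (1.71 ± 0.16) than in Col. Its ethylene effect was -0.67 ± 0.16 in Col and -1.80 ± 0.16 in aux1, a difference of -1.13 ± 0.23 that was not called (adjusted p = 0.139). YUC6, an auxin synthesis gene, stood at 0.59 ± 0.19 in ein2 against Col (adjusted p = 0.0736, and 0.0482 with a replicate block within each experiment). At the preset correlation only, the low-oxygen list weighed below was also called lower with IAA in Col (-0.40, adjusted p = 0.0144, and 0.395 with an estimated correlation) and in aux1 in air (-0.25, 0.0302, and 0.421) and in ethylene (-0.31, 0.0392, and 0.43), and higher for the IAA by ein2 difference (0.49, 0.000199, and 0.194). The reference genes AT4G34270 and AT2G28390 were not called in any of the 8 comparisons.

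Of the 74 genes higher in aux1 in air, 63 were also higher in ein2 in mock, against 3.96 expected (Fisher's exact p = 1.39e-69), among them AT5G37690 and AT2G35380. On a list of 21 suberin genes drawn up after some of these genes had been seen, and so not independent, 4 of 5 tested members were called higher in aux1 (median 4.03, camera adjusted p = 1.84e-13, and 0.0118 with an estimated correlation) and 5 in ein2 (4.00, 1.6e-07, and 0.0268), among them FACT, which makes suberin-associated waxes (4.03 and 3.00). Under both scalings 60 or more genes were shared. The deposited arrays were already close in scale, so this argues only against a scale difference left in the deposited values. A deviation of the Col control arrays is argued against, since the medians of the shared genes were 1.86 in aux1 against Col in ethylene and 3.02 in ein2 against Col in IAA. Shoot tissue on the roots cannot be told apart by the photosystem family, whose mean differed by 0.20 in aux1 and by -0.54 in ein2 (pooled SE 0.39 each, with 0 members called higher and 3 lower in ein2), since 2 SE allow a rise of up to 0.98 and 0.24 and the level of the family in dark-grown shoots was not measured here. The genotypes themselves stay among the open explanations, untested against differences in seed stock or age.

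On a list of 40 core low-oxygen genes, also drawn up after seeing values, 11 of 16 tested members were lower in ein2 than in Col in mock (median -2.07, camera adjusted p = 7.66e-15, and 0.0194 with an estimated correlation), among them AT4G10270 and AT1G19530, while the same list had medians of 0.75 with ethylene in Col and 0.70 in aux1 (adjusted p = 0.000347 and 0.000178, and 0.2 and 0.194 with an estimated correlation). A condition of the mock plates alone is argued against by a median of -1.41 between the IAA-treated genotypes, and a single array by medians of -1.95 or lower in all 4 pairs of arrays. A raised level in the sprayed Col plates met its test, at 0.53 above Col in air (adjusted p = 0.000924, and 0.228 with an estimated correlation). As the whole cause it is argued against, since the list mean in ein2 in mock differed from Col in air by -1.32 (pooled SE 0.21 over arrays), with 9 members called lower and 0 higher, although this comparison crosses the 2 experiments and its median of -0.96 (adjusted p = 1.04e-06) was not called with an estimated correlation (adjusted p = 0.0969). A candidate explanation beside it is that EIN2 signalling raises these genes, for which the list's change with ethylene is the only test made, and its call did not hold with an estimated correlation. The separate low-oxygen list fixed in advance had only 1 tested member, AT4G17260. Its mean was 7.24 in Col in mock and 7.21 in ein2 in mock, so it did not show the fall.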
